A study of Mus musculus with 2 samples.

How the data were processed

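The counts are raw UMI counts per gene and cell that the authors made with Cell Ranger 6.0.1 on build mm10, per the submitters' processing notes, from 10x Chromium 5' libraries, and deposited as filtered barcodes. UMIs are molecular tags that let each captured RNA be counted once. The annotation release is not given in the sources used here. Each genotype's matrix held 32285 genes and 4 hashtag features, which were kept out of all totals. A deposited hashtag sheet ties hashtags 1 and 2 to WT replicates 1 and 2 and hashtags 3 and 4 to NR4aDKO replicates 1 and 2, and gives the same reagent code for hashtags 3 and 4. Coordinates are 1-based positions from GENCODE release M21 on mm10, which held 32158 of the gene identifiers.

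Cells were kept with at least 500 detected genes, at least 1000 UMIs and under 10% mitochondrial UMIs, which removed 73 and 50 barcodes of the WT samples and 159 of NR4aDKO. A cell was given to a hashtag with at least 10 counts and at least 2 times the next hashtag, and all 4859 barcodes passed and matched their matrix's genotype. Doublet calling gave 0 calls among 4577 cells and removed nothing. Cells of 1 cluster led by dendritic cell markers were left out, 13, 1 and 9 in WT replicate 1, WT replicate 2 and NR4aDKO.

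Counts were summed per sample. The 2 NR4aDKO hashtags were summed to 1 sample after their counts were found to differ no more than random splits of the same cells, and before calls with 3 and 4 samples were compared. Genes with at least 20 CPM in 1 genotype were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on total-UMI scaling, two-sided, with Benjamini-Hochberg adjustment at 0.05. The p values rest on 2 WT sums and 1 NR4aDKO sum, and the lone sum is assumed to vary as the WT sums do. Ratios are NR4aDKO over the WT mean with a pseudocount of 1 CPM, and SE is that of the log2 ratio. Gene lists used genes with at least 5 CPM and camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation.

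Genes were named by a rule with 4 parts: Nr4a1, Nr4a2 and Nr4a3; the 12 highest and 12 lowest ratios among genes with at least 50 CPM, leaving out receptor and immunoglobulin segments, mitochondrial, ribosomal protein and sex-linked genes and predicted models; up to 4 members per list; and 12 genes for shares of cells. The version of the second part for designs without replicates was used, since NR4aDKO counted as 1 sample. The rule named 106 genes. The lists, the rule, the filters and most other settings tried were chosen before the data were examined. Genes outside the rule are said to be so where they appear.

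Shares of cells with a UMI were taken after thinning each cell to 3000 UMIs, leaving out shallower cells. Intervals are exact Clopper-Pearson 95% intervals, and a share of 0 is given with the limit of 3 cells of the total; both cover counting error only. Clusters came from Leiden clustering at resolution 0.6 on 30 principal components of 2000 variable genes with 15 neighbours, without receptor segments, the Nr4a genes and sex-linked genes (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). Shares between samples were taken from clusters formed again without the 114 genes that had an unadjusted edgeR p under 0.05. A cluster took a cell type's name with at least 2 of its markers among the top 10 genes, at least 3 raised by 1.5-fold and the list's first gene raised by 1.5-fold. This naming rule was changed after the clusters were seen: the first version named cluster 2 stem-like and left cluster 5 unnamed. Tests within clusters used clusters with at least 50 cells per genotype and 10 per WT sample.

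The test was tried on simulated counts over 10 runs. It called 505 of 974 genes changed 2-fold and 75 of 981 changed 1.5-fold, with 31 false calls. Camera called a list raised 1.3-fold in 10 of 10 runs and 1 of 250 other lists. These counts are not error rates for the real lists, whose genes can vary together between samples. They are also not to be compared with each other. Alternatives covered cell filters, TMM and median-of-ratios scaling, a mean over cells, G1 cells, other totals, gene minimums, pseudocounts, DESeq2 1.42.0, a replicate block, a stricter hashtag call, thinning, clustering settings and each replicate left out. Alternatives on donor sex, on the low-depth cluster, on the cluster that differed most between the WT samples and on 4 hashtags as 4 samples were chosen after seeing the data. Leaving out a WT sample leaves 1 against 1, so those values have no test. Matplotlib 3.10.9 drew the figures. The hashtag counts used are those inside the 2 matrices; the series' separate hashtag sample held no files of its own.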

Results

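The series holds single-cell RNA profiles of OT-I CD8 T cells, whose transgenic receptor recognises an ovalbumin peptide, recovered from B16-OVA melanomas grown in Rag2-deficient mice. The transferred cells came from wild-type (WT) donors or from donors whose floxed Nr4a1 and Nr4a2 genes were deleted by a Cd8-driven Cre recombinase (NR4aDKO). Nr4a1 and Nr4a2 encode nuclear receptor transcription factors that are induced by T cell receptor signals. Cells were transferred 10 days after tumour implantation and recovered 10 days after transfer, and the labels describe them as CD8 T cells positive for PD-1 and Tim-3, the proteins of Pdcd1 and Havcr2. Hashtag antibodies marked 2 WT and 2 NR4aDKO samples. The 2 WT samples held 1346 and 881 cell barcodes with 7568241 and 4660458 UMIs, medians of 4451.5 and 4096 UMIs per barcode. The NR4aDKO barcodes numbered 2632 with 12524079 UMIs, a median of 3755.5. After filtering, 1260 and 830 WT cells and 2464 NR4aDKO cells were compared.

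The 2 NR4aDKO hashtags differed by no more than sampling noise and were counted as 1 sample. Their counts over 9037 genes gave a chi-square of 1.301 per degree of freedom, and 25 of 100 random splits of the same cells gave a value as large. The same measure between the 2 WT samples was 11.1, above all 100 random splits. The comparison therefore set 1 NR4aDKO sample against 2 WT samples, with the lone NR4aDKO sample assumed to vary as the WT samples did, and a permutation of 1 sample against 2 cannot give an exact p below 0.333. Sex-linked transcripts also separated the genotypes. Of the NR4aDKO cells, 904 had UMIs of Xist, the X-inactivation RNA of female cells, and none of the Y-linked genes, and 331 had the reverse. In the WT samples 0 of 1260 and 0 of 830 cells had Xist UMIs alone, which allows a share of up to 0.238% and 0.361%, and 622 and 398 cells had Y-linked UMIs alone. Donor sex thus differed with genotype beside every comparison that follows. Neither signal was seen in 637 and 429 WT cells and 1181 NR4aDKO cells, so comparisons among cells with a Y-linked UMI also select cells.

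The first comparison addressed the targeted genes themselves. Nr4a1 (ENSMUSG00000023034, mm10 chromosome 15, 101254269 to 101274795) stood at 744 and 795 CPM (UMIs scaled to the sample total) in the WT samples and 1120 CPM in NR4aDKO, a log2 ratio of 0.54 (SE 0.178). Nr4a2 (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003) stood at 292 and 110.5 CPM against 324 CPM, a log2 ratio of 0.68 (SE 0.392). Nr4a3, the untargeted member of the family, stood at 183 and 72.15 CPM against 173 CPM. None passed edgeR's quasi-likelihood test (adjusted p 1.00 for each). Without WT replicate 2 the log2 ratio of Nr4a2 was 0.15 and that of Nr4a3 was -0.08, and without WT replicate 1 that of Nr4a2 was 1.54. Neither targeted gene was thus lower in RNA counted from NR4aDKO cells, but reads of a 5' assay come from the start of the transcript and the deleted exons are not given in the labels, so these levels do not check the genotype.

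The comparison of all genes asked which transcripts differ between tumour-infiltrating T cells labelled WT and NR4aDKO. Of 5653 genes tested, 2 rose and 8 fell in NR4aDKO at an adjusted p of 0.05 (edgeR), and 114 had an unadjusted p under 0.05. Ifi213, a member of the interferon-inducible Ifi200 family, rose from 11.4 and 9.10 to 49.6 CPM (log2 ratio 2.17, SE 0.265, edgeR adjusted p 0.00303). That rise followed the donors of NR4aDKO cells, by sex or by another difference between them: Ifi213 had a log2 ratio of -0.76 among cells with a Y-linked UMI and no Xist UMI. Within NR4aDKO, Ifi213 was 3.38 log2 units higher in cells with Xist UMIs alone than in cells with Y-linked UMIs alone. The granule protease gene Gzma (chromosome 13, 113093825 to 113100981) fell from 1108 and 1351 to 504 CPM (log2 ratio -1.29, SE 0.198, edgeR adjusted p 0.0162). The chemokine gene Ccl1 (chromosome 11, 82176657 to 82305690) fell from 85.4 and 82.55 to 22.4 CPM (log2 ratio -1.86, SE 0.239, edgeR adjusted p 0.00439). WT replicate 1 had its higher Ccl1 level in cluster 2 and WT replicate 2 in cluster 6, as given below. NR4aDKO lay between them in both clusters, and the call was lost when cluster 2 was left out. Ifitm1, an interferon-inducible membrane protein gene (chromosome 7, 140967221 to 140969825), fell from 179 and 489 to 44.1 CPM (log2 ratio -2.89, edgeR adjusted p 0.0272), and its log2 ratio was -3.44 without WT replicate 1 and -1.99 without WT replicate 2. Ube2c, which acts at mitotic exit, fell from 97.46 and 88.4 to 37.3 CPM (edgeR adjusted p 0.0498). Ube2c stood at 25.04 and 49.6 CPM in the 2 NR4aDKO hashtags, and without NR4aDKO replicate 1 its log2 ratio was -0.89 (edgeR adjusted p 0.646).

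The other genes past the threshold lay outside the naming rule or were sex-linked, and were named after their values were seen. Dnah8 (log2 ratio -1.665, edgeR adjusted p 0.0161) and the receptor segment Trav14-2 (log2 ratio -2.795, edgeR adjusted p 0.0162) fell. Xist (log2 ratio 6.32, edgeR adjusted p 7.01e-08) rose, and the Y-linked Ddx3y (log2 ratio -1.70) and Eif2s3y (log2 ratio -1.48) fell, with edgeR adjusted p of 0.0161 and 0.0162. Counts of Ifi213, Ifitm1 and Trav14-2 are uncertain where reads fall on near-identical family members. The list of passing genes was not stable. Xist alone passed with TMM scaling, with median-of-ratios scaling, without the cell filter and with the stricter cell filter.

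By size, 28 genes were higher and 66 lower in NR4aDKO by at least 1.5-fold, and 7 and 17 by at least 2-fold. Of the 5653 genes, 21.8% lay above both WT samples and 29.7% below both, where chance gives 33.3% each. The 12 highest ratios among 2693 eligible genes belonged to Ier5l, Tsc22d3, Cxcr4, Nr4a2, Gdpd3, Ms4a4c, Plcxd2, Cebpb, Nr4a1, Ighm, Tigit and Ifit3, with log2 ratios from 0.85 to 0.52. Each of these 12 lay above both WT samples, which picking by the ratio favours, and none passed the test. Tsc22d3, a glucocorticoid-induced gene also called Gilz, stood at 131 and 338 CPM in WT and 418.5 CPM in NR4aDKO. The chemokine receptor gene Cxcr4 stood at 35.7 and 61.75 against 84.2 CPM, and its log2 ratio of 0.78 was 0.33 among cells with a Y-linked UMI and no Xist UMI. The inhibitory receptor gene Tigit stood at 120.4 and 135 against 184 CPM. Several of these ratios rest on 1 WT sample: Ier5l had a log2 ratio of 0.24 without WT replicate 2, and Tsc22d3 one of 0.31 without WT replicate 1.

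The 12 lowest ratios belonged to Ifitm1, Ccl1, Ube2c, Gzma, Cdc25b, Ifng, Ifitm2, Cdkn1a, Lgals3, Birc5, Ifitm3 and H2afx, with log2 ratios from -2.89 to -0.84. Of these 12, 11 lay below both WT samples, which picking by the ratio favours too. Ifng, the gene of the effector cytokine interferon gamma, stood at 376.5 and 362 CPM in WT and 178.5 CPM in NR4aDKO (log2 ratio -1.04, SE 0.242, edgeR adjusted p 0.252 over all genes and 0.0499 adjusted over the list alone, which here means the 311 tested genes of all 34 lists). The galectin gene Lgals3 stood at 368 and 508 against 236.5 CPM (edgeR adjusted p 0.840). Cdkn1a stood at 136 and 45.1 against 46.85 CPM, so its ratio came from WT replicate 1. With every sample given the same cluster shares the log2 ratios were -0.28 for Gzma, -0.16 for Ifitm2, -0.30 for Lgals3, -0.37 for Birc5 and -1.50 for Ifitm1, and that of Ifit3 was 0.18. These genes were not left out before that clustering and each was among the top 10 genes of a cluster, so part of each drop can follow from the clustering.

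**Figure D1:**
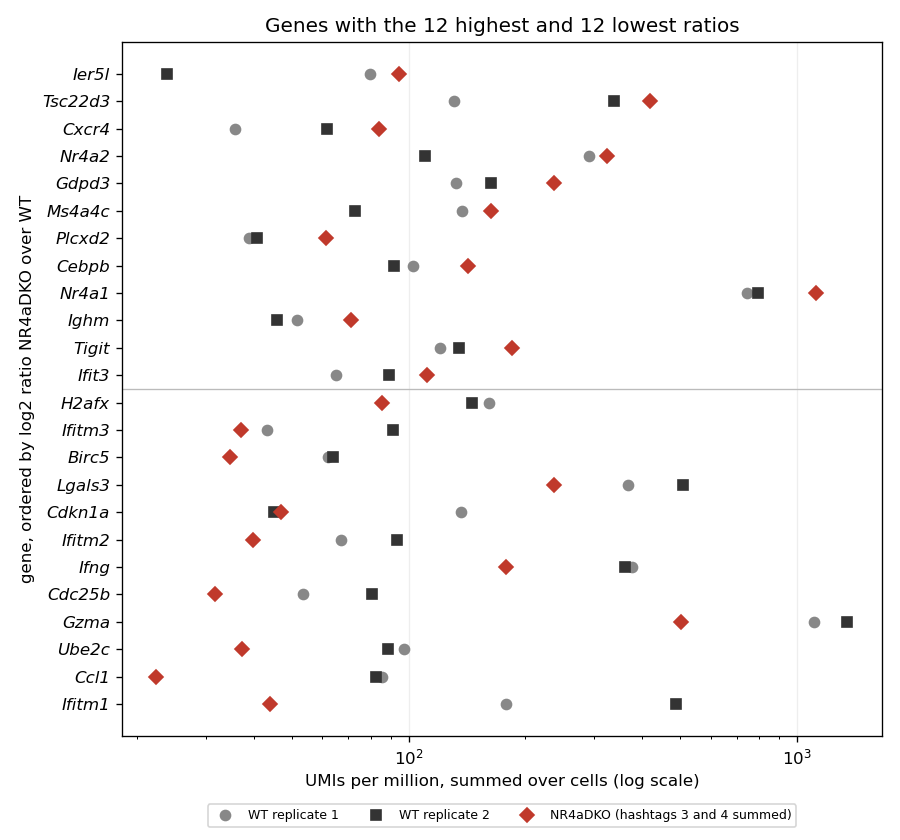
CPM on a log axis for the genes with the 12 highest and 12 lowest ratios, with each WT sample and the summed NR4aDKO sample as separate points. Ifng lies at 376.5 and 362 CPM in the WT samples and at 178.5 CPM in NR4aDKO, while Ier5l and Cdkn1a show WT samples that lie apart from each other.

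Groups of genes were compared through 34 lists fixed beforehand. Of their 311 tested genes, 4 passed over all genes and 5 when adjusted over the list alone, that is over these 311 genes, and 36 had an unadjusted p under 0.05. With camera at a preset correlation, 10 of the 27 lists with at least 3 measured genes passed, 4 upward and 6 downward. With a correlation estimated from these samples 0 of 27 passed, and the lowest adjusted p was 0.697. With so few samples that version could hardly pass, so it cannot decide whether a list differs. The NR4A family list had an estimated correlation of -0.333, lower than the preset one. Its unadjusted camera p still went from 4.36e-05 to 0.151. The S phase list had an estimated correlation of 1. The list results below therefore rest on the preset correlation, which these samples cannot check.

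Among cytokine and granule genes, Ccl1 and Gzma fell in NR4aDKO over all cells. Within clusters 2 and 6, Ccl1 in NR4aDKO lay between the WT samples, as given below. Of 12 tested cytokine and chemokine genes, Ifng passed beside Ccl1 when adjusted over the 311 genes of all lists, 6 lay below both WT samples and 0 above both. The list's median log2 ratio was -0.43 (camera adjusted p 1.43e-08 with the preset correlation). The adjusted p was 0.697 with an estimated correlation. Xcl1 stood at 691 and 172 CPM in WT against 309.8 CPM over all cells. In cluster 2 it stood at 1387 and 1426 against 773 CPM (edgeR adjusted p 0.00912). It is among the top 10 genes of that cluster, as Ccl1 is, so its levels there can follow in part from the clustering. Of 12 tested cytotoxic granule genes, Gzma fell and 11 did not pass. Gzmb, the granzyme B gene, stood at 1567 and 982 CPM in WT against 829 CPM in NR4aDKO, and Gzmc at 18.0 and 56.3 against 8.15 CPM, each at an edgeR adjusted p above 0.3. The granule list had a median log2 ratio of -0.10 and a mean of -0.36 (camera adjusted p 0.000192 with the preset correlation), and an adjusted p of 0.697 with an estimated correlation. Among cells with a Y-linked UMI and no Xist UMI the granule list had a camera adjusted p of 0.125. Without the cluster that differed most between the WT samples the cytokine list had a median of -0.03 and a camera adjusted p of 0.308, and without WT replicate 1 its median was -0.13. Within clusters its median was 0.34 in cluster 4 and 0.22 in the cycling-like cluster, and from -0.47 to -0.09 in the others.

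Most genes of the late cell cycle lay below both WT samples in NR4aDKO. Of 40 measured genes of the G2 and M phase list, 36 lay below both WT samples. The list's median log2 ratio was -0.53 (camera adjusted p 7.48e-32 with the preset correlation), and the adjusted p was 0.697 with an estimated correlation. Ube2c fell, while Mki67, a proliferation marker, stood at 127 and 130.4 CPM in WT against 77.8 CPM in NR4aDKO, and Birc5 at 62.0 and 63.9 against 34.6 CPM without passing the test. The overlapping cycling list had a median of -0.45 (camera adjusted p 9.30e-16 with the preset correlation), with an adjusted p of 0.697 with an estimated correlation. The S phase list had a median of -0.17 (camera adjusted p 0.00684 with the preset correlation), with an adjusted p of 0.940 with an estimated correlation, and its median was 0.04 without WT replicate 1. Among cells with a Y-linked UMI and no Xist UMI the medians were -0.15 for G2 and M, -0.10 for cycling and 0.08 for S phase, and among cells called G1 the G2 and M median was 0.07. Within NR4aDKO, Mki67 differed by -0.05 log2 units between cells with Xist UMIs alone and cells with Y-linked UMIs alone, and donor sex was not tested as the cause for these lists. Cells with neither signal were outside the Y-linked set, so its medians can also reflect which cells it holds.

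So did most genes of cholesterol synthesis. Of 18 measured members 15 lay below both WT samples, and 0 of 7 tested members passed singly. The median log2 ratio was -0.38 (camera adjusted p 2.57e-09 with the preset correlation), and the adjusted p was 0.697 with an estimated correlation. Insig1, which regulates sterol sensing, stood at 45.6 and 36.6 CPM in WT against 24.7 CPM in NR4aDKO, and Cyp51, a sterol demethylase gene, at 37.0 and 23.8 against 21.3 CPM.

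Most interferon-inducible genes of the fixed lists lay above both WT samples in NR4aDKO, while the Ifitm genes lay below both. Of 25 measured genes of the type I interferon response list 18 lay above both WT samples, and Ifi213 rose, with the dependence on donor given above. The list's median log2 ratio was 0.27 (camera adjusted p 2.495e-11 with the preset correlation), and the adjusted p was 0.697 with an estimated correlation. Ifit3 stood at 65.2 and 89.3 CPM in WT against 111.5 CPM, and Rtp4 at 69.3 and 67.4 against 96.9 CPM. The overlapping marker list of interferon-responding cells had a median of 0.27 (camera adjusted p 4.81e-05 with the preset correlation), with an adjusted p of 0.697 with an estimated correlation, and its median was 0.04 without WT replicate 2. Within clusters the type I list had smaller medians, from -0.07 to 0.14, and in the interferon-responding-like cluster 2 of 24 members lay above both WT samples and 2 below both. Ifitm1, Ifitm2 and Ifitm3, which belonged to no list, had log2 ratios of -2.89, -0.99 and -0.84. Ifitm3 stood at 43.2 and 91.2 CPM in WT against 37.1 CPM. Its log2 ratio was -1.28 without WT replicate 1 and -0.21 without WT replicate 2.

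Lists of exhaustion and stem-like genes had small median ratios. The stem-like precursor list, headed by the transcription factor gene Tcf7, had a median log2 ratio of 0.13 (camera adjusted p 0.0339 with the preset correlation). Its adjusted p was 0.697 with an estimated correlation, and its median was 0.01 without WT replicate 1. Tcf7 stood at 186 and 219.9 CPM in WT against 221.5 CPM in NR4aDKO, and Slamf6 at 52.65 and 64.6 against 83.5 CPM (edgeR adjusted p 1.00 for both). The terminally exhausted list had a median of -0.20 (camera adjusted p 0.345), the inhibitory receptor list one of 0.05 (0.815) and the list of exhaustion and NFAT transcription factors one of -0.14 (0.292). Within clusters, where lists were not tested, the terminally exhausted median was 0.10, 0.12, 0.29, 0.11 and 0.38 in clusters 1, 3, 4, 5 and 6 and -0.14 and -0.01 in clusters 2 and 7. The inhibitory receptor median was 0.09, 0.15, 0.21, 0.12 and 0.52 in clusters 1, 3, 4, 5 and 6 and -0.14 and -0.18 in clusters 2 and 7. In cluster 6, 8 of its 12 members lay above both WT samples, and in cluster 2, 7 of 11 lay below both. The genes of the labelled surface proteins, Havcr2, at 47.3 and 48.75 against 39.4 CPM, and Pdcd1, outside the naming rule, at 50.2 and 34.5 against 38.5 CPM, did not pass. The NR4A family list, made of the 2 targeted genes and Nr4a3, had a median of 0.54 (camera adjusted p 0.000168 with the preset correlation), with an adjusted p of 0.697 with an estimated correlation. Over the other settings tried its median ranged from 0.15 to 1.25.

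The remaining 17 tested lists did not pass, with camera adjusted p from 0.0706 for IL-2 and STAT5 signalling to 0.966 for CD8 T cell and NK cell markers. Their median log2 ratios included -0.23 for IL-2 and STAT5 signalling, 0.14 for costimulatory receptors, 0.05 for memory and stem transcription factors, 0.02 for immediate early genes, -0.07 for tissue residency and migration, -0.03 for glycolysis and hypoxia, -0.07 for oxidative phosphorylation, 0.01 for heat shock, -0.09 for apoptosis, 0.06 for NK receptors and -0.06 for effector genes. Signs differed in 5 lists: the mean was -0.02 for inhibitory receptors, -0.04 for immediate early genes and -0.10 for NK receptors, 0.15 for CD4 or regulatory T cells, and camera's direction for tissue residency was up. Within the IL-2 and STAT5 list, Cish, a feedback inhibitor of cytokine signalling, stood at 190 and 160 CPM in WT against 100.1 CPM. Markers on the lists of other cell types, most of them outside the naming rule and named after their values were seen, ranged from 0 cells to many. In WT replicate 1, WT replicate 2 and NR4aDKO, Ccr2 of the macrophage list was seen in 544, 471 and 1197 cells, Ighm of the B cell list in 262, 149 and 650 and Pecam1 of the endothelial list in 172, 103 and 363. Cd68 was seen in 88, 37 and 80 cells, Cd74 in 82, 24 and 97 and Lyz2 in 9, 3 and 10. Cd40lg of the CD4 list was seen in 70, 60 and 256 cells (log2 ratio 0.87, edgeR adjusted p 1.00). Of the melanoma list, Trpm1 was seen in 26, 0 and 2 cells and Pmel and Mlana in at most 5 cells of a sample. Cd4 was seen in 1, 0 and 1 cells, Csf3r of neutrophils, Clec9a of dendritic cells and Dcn of fibroblasts in 0 cells of each sample, and Hba-a1 of erythroid cells in 1, 0 and 0 cells. The lists of CD4 or regulatory T cells and of NK cells had medians of -0.02 and -0.07.

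**Figure D2:**
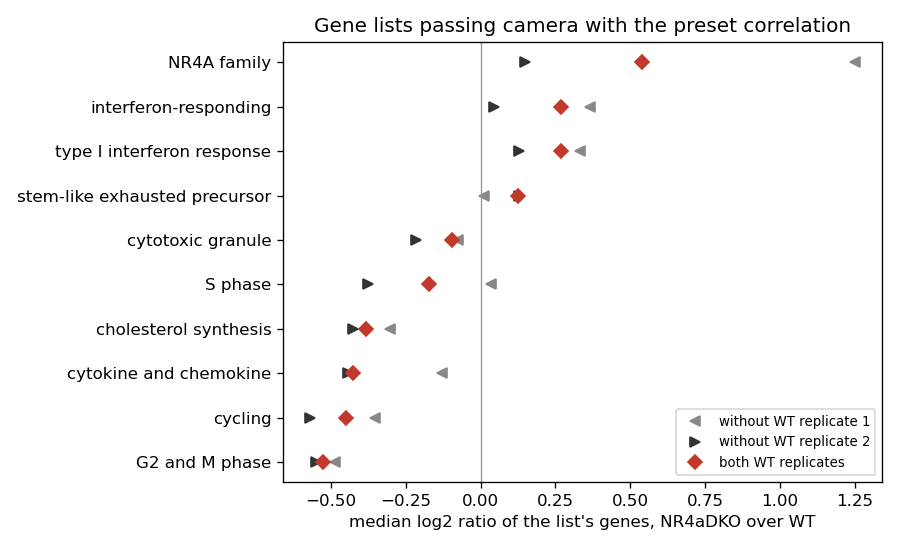
Median log2 ratio, NR4aDKO over WT, of the 10 gene lists that passed camera with the preset correlation, with the median against both WT replicates and against each alone. The G2 and M phase list lies at -0.53 and stays below 0 without either WT replicate, while the S phase list moves to 0.04 without WT replicate 1.

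The next comparison set side by side the share of cells with at least 1 UMI of each of 12 genes after thinning to 3000 UMIs per cell. Gzmb was seen in 63.4% (60.3 to 66.4%) and 58.3% (54.4 to 62.1%) of WT cells and in 50.1% (47.8 to 52.4%) of NR4aDKO cells, with exact 95% binomial intervals that cover counting error only. Ifng was seen in 35.2% and 47.65% of WT cells and 28.8% of NR4aDKO cells, and Mki67 in 11.2% and 9.56% against 6.31%. Slamf6 was seen in 14.3% and 16.5% against 21.55%, and Tcf7 in 36.7% and 41.0% against 44.2%. Havcr2 was seen in 9.11% and 12.6% against 7.68%, and Cd101 in 3.85% and 3.04% against 4.77%. Il7r, at 24.9% and 53.1% against 46.4%, and Klrg1, at 2.53% and 0.759% against 0.822%, lay between the WT samples. The labels describe the cells as positive for PD-1 and Tim-3, which can set these shares, but whether a gate was applied to the sequenced cells is not given in the sources used here. Pdcd1 UMIs were seen in 10.5% and 7.44% of WT and 8.22% of NR4aDKO cells.

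As background, 23 cells of a dendritic-cell-like cluster with a median of 9108 UMIs, against 4782 for the T cells, had Gzmb UMIs in 39.1%, Il7r in 34.8%, Tcf7 and Ifng in 17.4%, Slamf6 and Id3 in 13.0%, Cx3cr1 in 8.70%, Havcr2 and Entpd1 in 4.35% and Mki67, Klrg1, Cd101 and Pdcd1 in 0%, where 0 of 23 cells allows a share of up to 13.0%. No difference is read for Id3 (5.16%, 7.13% and 7.51%), Entpd1 (3.75%, 3.95% and 2.96%) and Cx3cr1 (2.63%, 1.21% and 1.15%), whose shares lay at or below it. For Mki67, Cd101, Klrg1 and Pdcd1 these cells cannot decide. A count of 0 of 23 shows no background but allows up to 13.0%, above their shares, so no difference is read. For Gzmb the background interval was 19.7 to 61.5%, which covers the shares of NR4aDKO and of WT replicate 2. Whether the UMIs in these 23 cells are stray or the cells' own was not tested. Thinning left out 272 and 171 WT cells and 640 NR4aDKO cells. Without thinning, Gzmb was seen in 68.65%, 62.2% and 55.6%, Ifng in 44.9%, 55.9% and 36.0%, Mki67 in 13.9%, 14.1% and 8.60%, Slamf6 in 21.2%, 27.7% and 28.65% and Tcf7 in 45.4%, 49.9% and 51.6% of WT replicate 1, WT replicate 2 and NR4aDKO cells. The share of cells called S or G2/M was 53.0% and 51.9% in WT and 50.3% in NR4aDKO after thinning, and no cycling is read from it alone.

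Cluster shares were compared with 114 genes left out before clustering, those with an unadjusted edgeR p under 0.05 between the genotypes. That is fewer than this threshold gives by chance among 5653 genes, so most of them are not shown to differ. Names and markers are those of the clusters formed with all variable genes, each matched to the new cluster with the largest overlap. The overlap, cells in both over cells in either, was 0.67, 0.82, 0.655, 0.61 and 0.57 for clusters 1 to 5. It was 0.88 to 0.96 for clusters 6 to 8. All 10 top genes of cluster 4 had been left out. The WT samples differed from each other more than either did from NR4aDKO in several clusters. Cluster 2, marked by Xcl1, Tnfrsf9, Ccr7 and Irf8 and left unnamed, held 30.6% (28.1 to 33.3%) of the cells of WT replicate 1, 2.77% (1.77 to 4.13%) of WT replicate 2 and 16.4% (14.95 to 17.9%) of NR4aDKO. Cluster 1, marked by Il7r, Tsc22d3 and Hspa1b, held 17.9% and 28.55% of WT cells and 40.3% (38.4 to 42.3%) of NR4aDKO cells. Cluster 4, marked by Ifitm1, Gzma, Lgals3 and S100a4, held 16.75% and 21.6% against 8.56% (7.49 to 9.74%). The stem-like precursor cluster held 6.03% and 14.5% against 7.87%, the interferon-responding-like cluster 11.9% and 20.5% against 19.2%, the cycling-like cluster 5.08% and 6.15% against 3.17%, the low-depth cluster 7 held 4.44% and 4.94% against 3.21%, and the effector-like cluster 4.05% and 0.241% against 1.22%. No cluster's abundance passed edgeR's test on the clusters formed with all variable genes (lowest adjusted p 0.534), and a gate on PD-1 and Tim-3 can set these shares too.

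**Figure D3:**
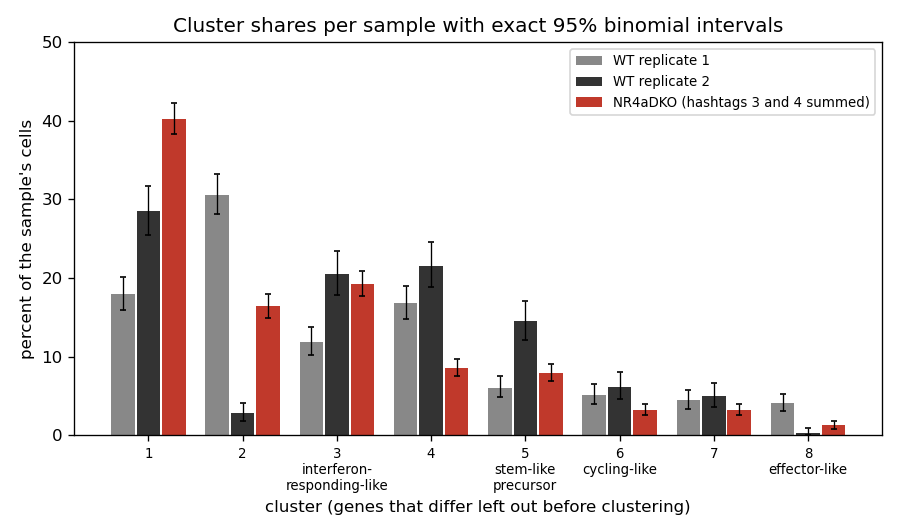
Percent of each sample's cells in 8 clusters formed without the 114 genes at an unadjusted edgeR p under 0.05, as bars from 0 with exact 95% binomial intervals. Labels are those of the matched clusters formed with all variable genes. Cluster 2 holds 30.6% of WT replicate 1, 2.77% of WT replicate 2 and 16.4% of NR4aDKO, and clusters 1 and 4 place NR4aDKO above and below both WT samples.

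Within clusters the comparison asked whether these differences were also seen among like cells, using the clusters formed with all variable genes. Cluster 2 held 385 cells of WT replicate 1, 30 of WT replicate 2 and 404 of NR4aDKO, so its WT replicate 2 values rest on 30 cells. In cluster 2, Ifng fell from 589 and 361 to 177 CPM (log2 ratio -1.42, SE 0.258, edgeR adjusted p 0.00428) and Ifitm1 from 59.7 and 96.4 to 12.5 CPM (edgeR adjusted p 0.000112). Nr4a1 rose there from 682 and 448 to 1286 CPM (log2 ratio 1.19, SE 0.193, edgeR adjusted p 0.00398). In the cycling-like cluster Gzma fell from 1274 and 2748 to 951 CPM (edgeR adjusted p 0.00819). It passed in no other cluster: in cluster 4, where it was most abundant, it stood at 3795 and 3904 against 3453 CPM (log2 ratio -0.16, edgeR adjusted p 0.985), and its log2 ratio was 0.07 in cluster 1. The log2 ratios of Gzma were -0.61, -0.36, -0.53 and -0.81 in clusters 2, 3, 5 and 7. In clusters 1, 2, 3 and 5 NR4aDKO lay between the WT samples. Ifng passed in cluster 2 alone, with log2 ratios from -0.75 to -0.25 in the others. Ccl1 stood at 196.8 and 38.55 against 57.5 CPM in cluster 2 (edgeR adjusted p 0.113). In cluster 6, the cycling-like cluster, it stood at 4.97 and 693.7 against 89.45 CPM (edgeR adjusted p 0.929). NR4aDKO thus lay between the WT samples in both. In the cycling-like cluster Gzmc, Ifitm1, Cd7 and the histone variant gene H2afx fell as well, with edgeR adjusted p from 4.66e-05 to 0.00426. Gzmc stood there at 60.9 and 422 CPM in WT against 16.8 CPM, and Ifitm1 at 106 and 628 against 27.4 CPM. NR4aDKO lay below both WT samples, but the size of these 2 falls rests largely on WT replicate 2. Tnfrsf4, the costimulatory receptor gene of OX40, rose there from 34.8 and 24.5 to 97.9 CPM (edgeR adjusted p 0.00761), and the chemokine gene Cxcl10, which is outside the naming rule and was chosen after its values were seen, rose from 80.8 and 33.9 to 201 CPM (edgeR adjusted p 0.00165). In the stem-like cluster Tcf7 stood at 558 and 520.2 CPM in WT against 415 CPM in NR4aDKO (edgeR adjusted p 0.996). Gzma was among the top 10 genes of cluster 4, Ccl1 of cluster 2 and Tcf7 of the stem-like cluster. Their levels within those clusters can follow in part from the clustering. Whether the effects within clusters differ between clusters was not tested. Over the 7 clusters the list medians, also untested, ranged from 0.38 to 0.74 for the NR4A family, -0.12 to 0.33 for stem-like precursors, -0.19 to 0.12 for granule genes, -0.25 to 0.19 for S phase and -0.33 to 0.11 for cycling. In all, 30 genes passed in at least 1 of the 7 clusters used, sex-linked genes among them, and clusters 8 and 9 held too few cells to be used. In cluster 2 they included Il17a, Il22, Il2 and Ccl9, which are outside the naming rule. Il17a stood there at 50.1 CPM in WT replicate 1 and 0 CPM in WT replicate 2 and NR4aDKO (edgeR adjusted p 0.000112). All of these stood at 0 CPM in WT replicate 2, so a pass in cluster 2 can rest on WT replicate 1 alone.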

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

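The test of whether 1 pool of cells carried both NR4aDKO hashtags was chosen after the result was seen.

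Xist UMIs without Y-linked UMIs were seen in 904 NR4aDKO cells and in 0 cells of either WT sample, a signal in genes left out of the comparisons. For the 24 genes with the highest and lowest ratios, a median fraction of 0.891 of the log2 ratio remained among cells with a Y-linked UMI and no Xist UMI (95% bootstrap interval 0.726 to 1.12), which argues against donor sex as the whole cause for the set. Donor sex stays open as the larger part for Cxcr4, which went from 0.78 to 0.33 and was 0.63 higher in Xist than in Y-linked cells of NR4aDKO. Birc5 went from -0.84 to -0.23 and Ube2c from -1.29 to -0.60. They differed by only -0.25 and -0.26 between Xist and Y-linked cells of NR4aDKO, so sex among those cells does not account for the whole of these drops. Cells with neither signal were outside this set, so a drop can also come from which cells it holds. At equal cluster shares a median fraction of 0.686 remained (0.586 to 0.873), which argues against composition as the whole cause for the set. It stays open as the larger part for Gzma (-1.29 to -0.28), Ifitm2 (-0.99 to -0.16), Lgals3 (-0.89 to -0.30), Birc5 (-0.84 to -0.37) and Ifit3 (0.52 to 0.18). The clusters used here were those formed without leaving out the 114 genes at an unadjusted edgeR p under 0.05. Each of these genes was among the top 10 genes of a cluster. Equal shares of such clusters can remove a gene's difference by construction, so these drops cannot tell composition from genotype. Genotype and other donor differences stay open, and Ifi213, outside the 24, went from 2.17 to -0.76 among cells with Y-linked UMIs.

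The 2 NR4aDKO hashtags were nearly identical. Their chi-square per degree of freedom was 1.301, within the 1.174 to 1.655 of 100 random splits of the same cells, while that of the WT samples was 11.1 against 1.22 to 1.895. This is consistent with 1 pool of NR4aDKO cells, of both sexes, that was stained with both hashtags. Cells given to the wrong NR4aDKO hashtag are argued against, since the second hashtag held 1.18% of the counts of both in the 95th percentile cell. Animals that happen to be alike stay open, and no biological explanation was tested.

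A dendritic-cell-like cluster held 13 cells of WT replicate 1, 1 of WT replicate 2 and 9 of NR4aDKO, a signal in cells left out of the comparisons.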

How the results depend on the processing

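The number of genes past an adjusted p of 0.05, 10 as reported, was 1 without the cell filter, 1 with the stricter filter, 1 with TMM and 1 with median-of-ratios scaling, 3 in G1 cells, 49 without a gene minimum, 5 at 100 CPM and 51 with a replicate block on the 4 hashtags, which gave 8 without the block. It was 0 with a mean over cells (limma, 109 at an unadjusted p under 0.05) and 0 in cells with a Y-linked UMI and no Xist UMI (edgeR, 64 at an unadjusted p under 0.05), while DESeq2 gave 10. The 4 hashtags without a block, the last of these cell sets, and the leave-one-out settings outside the gene tests, were chosen after seeing the data. Genes at least 1.5-fold apart, 94 as reported, numbered 566 without a gene minimum, 23 at 100 CPM, 190 in cells with Y-linked UMIs and 90 to 222 with a replicate left out. Of 492 other values of the 24 genes, 433 were counted as unchanged, 39 lost the call, 19 gained one and 1 reversed: Cdkn1a ranged from -1.52 to 0.0546 with a replicate left out. Unchanged means the same direction and side of the threshold. Without a WT replicate there is no test, and it means the same direction within the WT SD or the SE. That is lenient: Nr4a2 at 0.15 and 1.54 against 0.68 counts as unchanged. Most of the 24 did not pass, so unchanged mostly means not passing again. Of 149 values of the 10 passing lists, 129 were counted as unchanged in a similar way. The S phase median ranged from -0.37 to 0.0364 with a replicate left out and was 0.0781 in cells with Y-linked UMIs, and the G2 and M median was 0.0726 in G1 cells, which leave out cells called G2/M. In percentage points, the Tcf7 difference of 5.33 was 8.36 with the stricter filter, that of Il7r ranged from -6.73 to 21.5 and that of Klrg1 from -1.71 to 0.0637 with a replicate left out. The stem-like cluster's difference was 18.85 at resolution 0.3 and -5.72 to 1.49 with a replicate left out, the effector cluster's -2.465 to 1.34, and the interferon cluster's -11.5 at resolution 0.3 and -1.80 to 5.59. Within clusters, 50 genes passed at resolution 0.3 against 30. Fewer or more genes tested enter the counts at other gene minimums; for the other changes the cause was not tested. Simulated 1.5-fold changes were called in 7.645%, not split by depth.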

Other observations

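The test of neighbouring genes without overlaps was chosen after the pairs were seen, and the genes of clusters 2 and 9, the neighbouring genes and the receptor segment named here were chosen after their values were seen.

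The WT samples differed from each other in a set of cytokine genes. In cluster 2, Il17a stood at 50.1 CPM in WT replicate 1 and Il22 at 57.8 CPM, with 0 UMIs of either in WT replicate 2 and NR4aDKO, and Il2 at 69.0 CPM against 0 and 3.29 CPM. WT replicate 2 had 30 cells in that cluster and WT replicate 1 had 385. Il17a, Il22 and Il2 passed edgeR's test between genotypes there, as given above, although WT replicate 2 lay with NR4aDKO. Cluster 9, marked by Tmem176b, Tmem176a, Il17a and Rora, held 53 cells of WT replicate 1, 11 of WT replicate 2 and 8 of NR4aDKO. Trbv12-1, the OT-I beta segment under its gene name, was seen in 94.9% and 94.0% of WT cells and 96.1% of NR4aDKO cells, and made up 99.8%, 99.5% and 99.7% of all Trbv UMIs.

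In the cycling-like cluster, genes of cholesterol synthesis had a median log2 ratio of -0.49, with 10 of 11 measured members below both WT samples. The medians were -0.28, -0.39, -0.34 and -0.19 in clusters 1 to 4, and 0.26 and 0.34 in clusters 5 and 7. Genes of G2 and M phase had a median of -0.17 in the cycling-like cluster, with 28 of 40 below both, -0.30 in cluster 4, 0.03, 0.00466 and 0.00900 in clusters 1 to 3, and 0.27 and 0.33 in clusters 5 and 7. None was tested within a cluster.

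Some genes with an unadjusted edgeR p under 0.05 between genotypes lay near each other. Examples were Glo1, 1700097N02Rik and Dnah8 on chromosome 17 (log2 ratios -0.70, -1.17 and -1.665) and Rcn3, Fcgrt and Gm45552 on chromosome 7 (-0.78, -0.91 and -1.10). Among 101 autosomal genes at an unadjusted p under 0.05 there were 28 pairs within 2 Mb, where expression-matched random sets had a median of 17.0, a 95th percentile of 26 and as many in 3.6%. With overlapping genes such as 1700097N02Rik left out and each family counted once, in real and random sets alike, there were 17 pairs against a median of 15, and 34.96% had as many. Linked variants between donors or strains are therefore left undecided. Variants around the targeted genes are argued against for the pairs as a set, since 1 of the 28, Nr4a1 with Itgb7, lies within 5 Mb of them and the 61 genes there had a median absolute log2 ratio of 0.0889 against 0.0944 in random sets; for single genes such as Itgb7 (log2 ratio -0.58) they stay open.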
